A study of Mus musculus with 6 samples.

How the data were processed

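Poly(A) RNA from the mouse fibroblast line L929 was sequenced in 6 samples, 3 labelled control and 3 labelled STING KO. Per the labels' protocols, total RNA was isolated with TRIzol and mRNA was purified on oligo(dT) beads. Groups and replicate numbers were taken from the sample titles, and the genotype label of the control samples is WT. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

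The authors deposited 1 table of genes. Its 6 sample columns hold a signal that the authors made by dividing gene counts by a size factor of each sample, called normalized count below. This was read from the values: in each column 100% of the values above 0 were whole multiples, within 0.01, of 1 step, and the steps ran from 0.990 to 1.00. Per the file headers, the table also gives the authors' own comparison: a log2 fold change of STING KO over control with its standard error, a Wald score, a p-value and an adjusted p-value. Per the submitters' processing notes, which list tools with no role or order, the authors used HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5, and the builds named are GRCm38 and mm10. The annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared between them.

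The table has 27821 rows for 27507 gene identifiers. A further 314 rows repeat an identifier under another symbol, and only the first row of each was used. GENCODE M21, an annotation of GRCm38, holds 27480 of the identifiers and gave coordinates, gene types, transcript lengths and GC content. It also gave the symbol where a row carried a date in place of a symbol (27 rows) or where an identifier had several symbols.

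The sample totals were 14382072 to 14526606 in normalized counts, and 14445540 to 14582221 when divided by the step of each column, so depth was nearly equal. At this depth, the fit described next was tested on simulated data drawn for the same 12408 genes and the comparison of STING KO with control. It recovered 77.6% of 67 genes changed by 1.5-fold, 91.0% of 67 changed by 2-fold and 98.5% of 66 changed by 4-fold, and 9 of its 187 calls were unchanged genes. The simulation held no gradient shared by many genes, which the real libraries have. Within groups, pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of 2.41 to 10.6. This was taken over genes whose values, divided by the step and rounded, summed to more than 50. No library was thus taken for a repeat deposit.

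Because the values are normalized, the test planned for expected counts was replaced by the one planned for normalized values. This was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(normalized count + 0.1), for genes with a value of at least 10 in at least 3 samples. No covariate was used. Genes with a Benjamini-Hochberg adjusted p at or under 0.05 were called. Fold changes are on the log2(value + 0.1) scale, which can understate the change of low genes. It can also overstate it where some libraries list no counts of a gene. The authors' normalization was kept, and the gene test planned for expected counts was not run on these values. limma-voom, the chi-square given for hepatocyte markers and the interval given for Csf3 treated the values as counts. The chi-square of pairs of libraries used the values divided by the step of each column and rounded.

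The rule for named genes, the 25 gene lists, the main test and most alternatives were fixed before the data were examined. The rule takes Sting1, listed in the table under its older symbol Tmem173. It then takes the 6 largest changes in each direction among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups, skipping pseudogenes and genes without a name. Last, it takes the 2 largest changes among the called members of each list, with the same minimum. This gave 9 genes. The other 23 called genes are named where they help to describe a group, and those names were chosen after their values were seen.

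Lists with at least 5 tested members were compared with all other genes by camera, with a preset correlation of 0.01 and again with an estimated correlation. The fry test asked whether the members of a list moved, on balance, in 1 direction, which does not compare the list with other genes. All 3 were adjusted over the 23 lists tested. Shares of the total were compared by an exact two-sided permutation test, whose smallest p for 3 samples against 3 is 0.1.

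Other settings fixed in advance for genes were upper-quartile scaling, limma-voom on the deposited values with equal library sizes, no filter, a minimum mean of 5 CPM, a replicate block, a pseudocount of 1, a fold threshold of 1.5, leaving out each library, and the authors' deposited test. Chosen after seeing the data were TMM and total scaling, limma-voom with its default library sizes and with a block, and a correction for GC content and transcript length. That correction removed a loess trend with a span of 0.3 from each library. Also chosen after seeing the data were 2 added covariates and the fit without the 2 libraries that hold hepatocyte transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.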

Results

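The transcriptome of L929 cells, a fibroblast line from mouse connective tissue, was measured by RNA-seq in 3 control samples and 3 samples with a knockout of STING. STING is the endoplasmic reticulum adaptor that passes the cyclic dinucleotide signal of the DNA sensor cGAS to TBK1, IRF3 and NF-kB. The series asks how its loss affects gene expression. The labels name no treatment, and values are normalized counts with totals of 14382072 to 14526606 per sample.

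Sting1 RNA was lower in every STING KO library than in every control library. The gene (Tmem173 in the table, ENSMUSG00000024349, chromosome 18, 35733679 to 35740554 on the minus strand in GRCm38, protein coding) was at 329, 313 and 311 normalized counts in the control libraries. In the STING KO libraries it was at 82.1, 80.6 and 93.4. The means were 318 ± 10.1 (SD, n = 3) and 85.4 ± 6.96 (SD, n = 3), a log2 fold change of -1.90 (SE 0.09, limma adjusted p = 9.72e-06). Thus 26.9% of the control level was left. These values go with the genotype labels of all 6 libraries. The level of an RNA does not show whether it still encodes protein.

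Several genes for chemokines, cytokines and regulators of NF-kB signalling were among those called lower in STING KO, and limma called 0 genes higher. The largest decreases among the genes named by the rule were in Cxcl1, Ccl2 and Ccl7, which encode chemokines that attract neutrophils and monocytes. Cxcl1 fell from 371 ± 27.4 to 18.2 ± 4.98 normalized counts (SD, n = 3 each), which is 4.91% of the control level. Ccl2 fell from 2356 ± 144 to 273 ± 14.4, to 11.6% of control, and Ccl7 fell from 700.2 ± 31.1 to 119 ± 1.56, to 17.0% of control (SD, n = 3 each). Of 12408 genes tested, 32 were lower in STING KO, 10 of them by 2-fold or more and 22 by less.

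The log2 fold changes of these chemokine genes were -4.37 (SE 0.18, limma adjusted p = 2.9e-06) for Cxcl1, -3.11 (SE 0.07, adjusted p = 2.53e-08) for Ccl2 and -2.55 (SE 0.07, adjusted p = 1.3e-07) for Ccl7. Cxcl1 (ENSMUSG00000029380) lies on chromosome 5 at 90891241 to 90893115. Ccl2 (ENSMUSG00000035385, 82035571 to 82037453) and Ccl7 (ENSMUSG00000035373, 82045712 to 82047525) are neighbours on chromosome 11. Zc3h12a, which encodes the RNase Regnase-1 that degrades cytokine mRNAs, had a log2 fold change of -1.93 (SE 0.07, adjusted p = 1.8e-06) and was left at 26.2% of control. Cd40, a receptor of the TNF receptor family, had a log2 fold change of -1.11 (SE 0.09, adjusted p = 0.000773). Smaller decreases were called in Junb, an AP-1 transcription factor subunit (-0.66, SE 0.06, adjusted p = 0.001), in Col8a1, a collagen chain (-0.69, SE 0.11, adjusted p = 0.0428), and in Fgf7, a growth factor for epithelial cells (-0.45, SE 0.07, adjusted p = 0.0312). Of these, Col8a1 and Fgf7 lost their calls in several fits that left out 1 library. Their log2 fold changes stayed at -0.75 to -0.58 and at -0.50 to -0.41 in these fits. Col8a1 was at an adjusted p of 0.165, 0.0681 and 0.202 without control replicates 1, 2 and 3, at 0.165 and 0.0618 without STING KO replicates 1 and 2, and called only without STING KO replicate 3. Fgf7 was at 0.237 and 0.202 without control replicates 1 and 3 and at 0.242 without STING KO replicate 1.

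**Figure D1:**
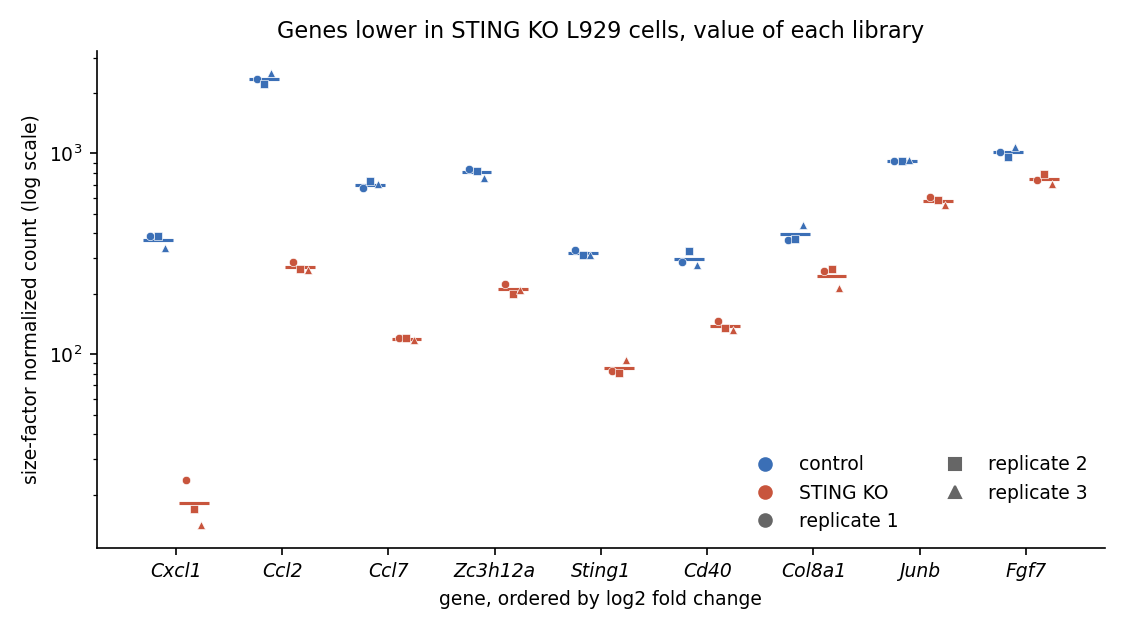
Normalized count on a log axis of each library for Sting1 and the other genes named by the rule, with control in blue, STING KO in red, a symbol for each replicate number and a line at each group mean. For all 9 genes the 3 STING KO values lie below the 3 control values, from 4.91% of the control mean for Cxcl1 to 73.1% for Fgf7.

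The list of NF-kB target genes stood out among the 25 lists. Of its 28 tested members, 12 were called lower, 0 were called higher and 16 were not called; adjusted over the list alone, 20 were lower. Chance would place 0.0722 members among the 32 called genes (Fisher's exact test, one-sided p = 2.43e-25, over the 12408 genes tested). The list was lower than other genes by camera with the preset correlation (adjusted p = 8.97e-35) and with an estimated correlation (adjusted p = 0.00583), and fry gave an adjusted p of 0.000122. Relative to the control mean, its mean log2 value was -0.85, at -0.72, -0.85 and -0.98 in the 3 STING KO libraries. Beside the chemokines, the called members included the cytokine gene Il6 (log2 fold change -2.30, SE 0.20, 20.2% of control) and Csf1, the macrophage growth factor, which fell from 14947 ± 272 to 10735 ± 515 normalized counts (SD, n = 3 each).

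Several of the called members encode parts or inhibitors of the NF-kB pathway itself. Nfkbia, the inhibitor IkB alpha, was at 55.3% of control, Nfkbiz at 56.5%, Relb at 52.0%, Nfkb2 at 78.0% and Tnip1 at 65.7%. The remaining called members were Irf1, a transcription factor of interferon responses, at 72.5% of control and Lif, a cytokine of the interleukin-6 family, at 57.8%. Leaving out 1 library ended the calls of Nfkb2 (adjusted p of 0.237 and 0.181 without control replicates 1 and 3, and 0.217 without STING KO replicate 1) and of Irf1 (0.209 and 0.148 without the same control replicates, and 0.182 and 0.077 without STING KO replicates 1 and 2). It also ended that of Lif, at 0.121 and 0.202 without control replicates 2 and 3 and at 0.22 and 0.0997 without STING KO replicates 1 and 2. Lcn2, encoding the iron-scavenging protein lipocalin 2, was not called. Its STING KO values were 146, 46.8 and 41.2 against 295, 319 and 347 in control (limma adjusted p = 0.0721).

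Of the 32 called genes, 17 stood in no list. Csf3, the granulocyte growth factor, had 22.6 ± 2.1 normalized counts in control (SD, n = 3) and about 1 in each STING KO library. With the values rounded to whole numbers, 68 against 3 in sum, this is a ratio of 22.7 with an exact 95% counting interval of 7.43 to 113. Osmr, the receptor chain of oncostatin M, was at 64.7% of control, the transcription factor genes Cebpd and Pou2f2 were at 54.7% and 58.3%, and Tlr2, a receptor for bacterial lipoproteins, was at 57.2%. The others were Sbno2, Slc11a2, Adamts7, Vmp1, Cp, Gypc, Slpi, Pik3r5 and the noncoding Gm6093, beside Sting1, Zc3h12a and Cd40. Their remaining levels ran from 29.4% of control for Gm6093 to 74.7% for Vmp1, leaving aside Sting1 and Zc3h12a. Tlr2 and Pik3r5 (adjusted p = 0.049 for both) were not called without any 1 of the 6 libraries, at 0.066 to 0.318 and 0.0564 to 0.302, and in the authors' table Tlr2 is at 0.209. Without control replicate 1, Csf3 (0.063), Vmp1 (0.0561), Cp (0.0631), Gypc (0.154) and Slpi (0.186) were not called either. The same held for Gypc (0.121) and Slpi (0.193) without control replicate 3, for Cp (0.0828) and Slpi (0.0783) without STING KO replicate 1, and for Gypc (0.0699) and Slpi (0.0868) without STING KO replicate 2.

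Interferon-stimulated genes did not move as a group. Of 45 tested members 0 were called, 42 had a 95% interval within 2-fold in both directions, and camera gave an adjusted p of 0.801. The member with the smallest p was Gbp2, an interferon-induced GTPase, at 37.9 ± 4.97 in control and 16.9 ± 0.95 in STING KO (SD, n = 3 each; adjusted p = 0.0796), and it was the 1 gene lower when adjusted over the list alone. The fry test for change in either direction gave an adjusted p of 0.0115 for this list. The other components of the STING pathway had 0 of 22 members called (camera adjusted p = 0.254). Cgas itself was at 136 normalized counts in control and 120 in STING KO (log2 fold change -0.18, SE 0.11, adjusted p = 0.738). MHC class I presentation had 0 of 21 called (camera adjusted p = 0.801), with B2m at 10565 and 10867 normalized counts, and 1 gene lower adjusted over the list alone, the transactivator gene Nlrc5 (log2 fold change -0.31, SE 0.07, adjusted p over all genes = 0.349).

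Glycolysis and hypoxia genes were higher in STING KO by camera with the preset correlation (adjusted p = 1.12e-16) but not with an estimated correlation (adjusted p = 0.274). None of the 30 members was called over all genes, while 18 were higher adjusted over the list alone and 27 had a positive sign. The mean log2 fold change was 0.18, the STING KO libraries stood at 0.12, 0.21 and 0.21, and fry gave an adjusted p of 0.0478. Ankrd37, a target of the hypoxia-inducible factor, was at 56.5 ± 5.97 in control and 95.3 ± 1.82 in STING KO (SD, n = 3 each; limma adjusted p = 0.0602). Ndrg1 was at 3657 ± 347 and 4805 ± 328 (SD, n = 3 each; adjusted p = 0.143). In the authors' deposited table Ndrg1 and Car9, carbonic anhydrase 9, were past the threshold, with adjusted p of 0.000575 and 0.0138.

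Ribosomal protein genes were also higher by camera (adjusted p = 9.8e-12) and not with an estimated correlation (adjusted p = 0.472). Of 49 members 0 were called and 45 had a positive sign, at a mean log2 fold change of 0.13. These genes have many near-identical pseudogenes, so their single values are uncertain. The libraries of the groups overlapped, with control replicate 2 at 0.12 and STING KO replicate 2 at 0.04. NRF2 and redox genes were higher (adjusted p = 0.0231; 0.621 with an estimated correlation) and p53 target genes lower (adjusted p = 0.0456; 0.467 with an estimated correlation). Neither list had a called member. Leaving out 1 library ended the call for NRF2 genes (0.126 without control replicate 1 and 0.336 without STING KO replicate 3) and for p53 targets (0.164 without control replicate 3, and 0.0599 and 0.208 without STING KO replicates 1 and 2). Gsta4, a glutathione transferase gene, was the 1 NRF2 list gene higher adjusted over the list alone, at 4071 normalized counts in control and 4881 in STING KO.

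**Figure D2:**
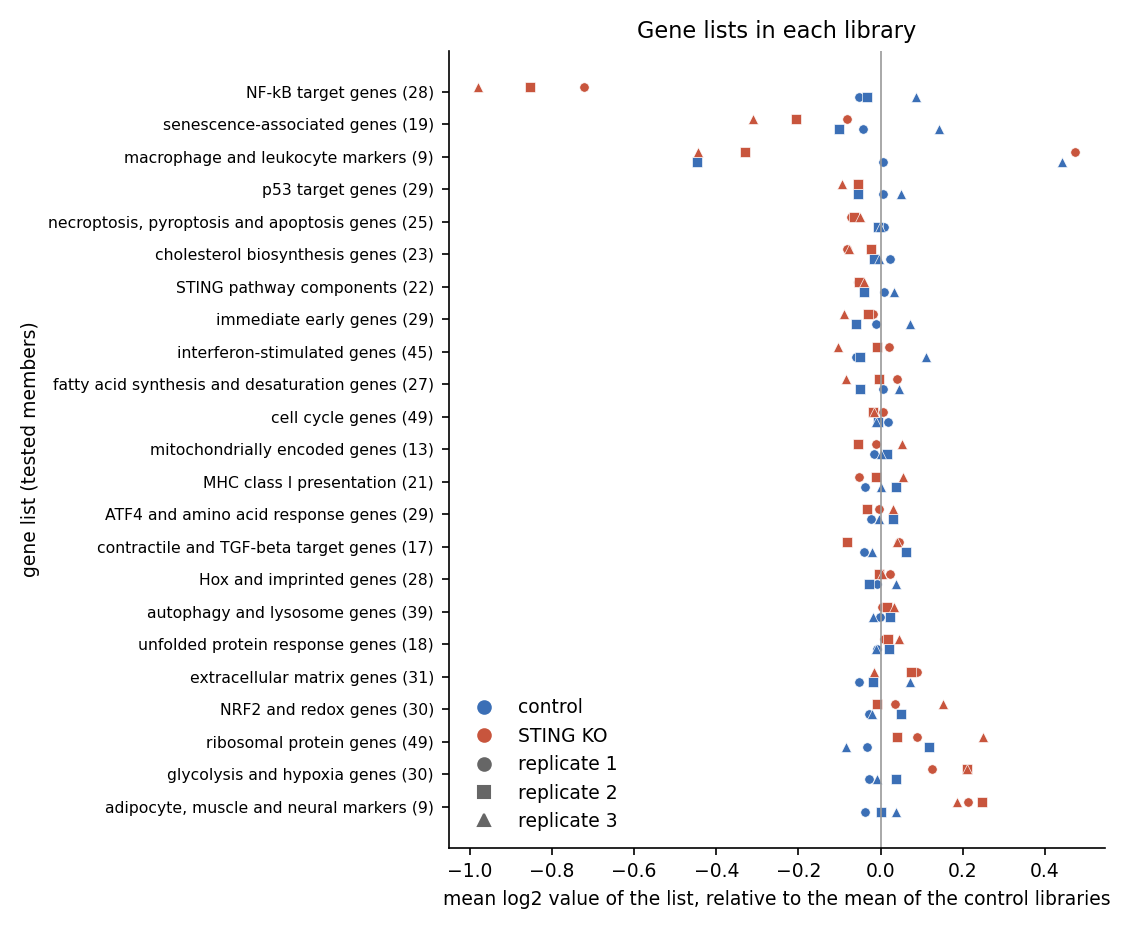
Mean log2 value of the members of each tested list in each library, relative to the mean of the control libraries, with control in blue, STING KO in red and the number of tested members in brackets. The NF-kB target genes lie at -0.72 to -0.98 in STING KO, and the leukocyte markers are high in control replicate 3 and STING KO replicate 1.

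Of the 23 tested lists, 18 were not past the threshold, the interferon, STING pathway and MHC lists among them. Senescence-associated genes had 2 of 19 called lower (Il6 and Fgf7), immediate early genes 1 of 29 (Junb) and extracellular matrix genes 1 of 31 (Col8a1), with camera adjusted p of 0.249, 0.253 and 0.0646. The camera direction was lower for the senescence-associated and immediate early genes but higher for the extracellular matrix genes. Of the matrix genes, 20 had a positive and 11 a negative sign, at a mean log2 fold change of 0.05. Without some single libraries Fgf7 and Col8a1 were not called, at adjusted p up to 0.242 and 0.202. Adjusted over the list alone, 3, 2 and 1 members of these lists were lower. For senescence-associated genes the median log2 fold change was 0.01 and the mean -0.20, and fry gave an adjusted p of 0.00277. Cell cycle genes had 0 of 49 called, each with a 95% interval within 2-fold (adjusted p = 0.855). Cholesterol biosynthesis, with 0 of 23 called, had an adjusted p of 0.0607, and fatty acid synthesis, with 0 of 27, had 0.801. The death pathway genes (0 of 25, 0.163), the autophagy and lysosome genes (0 of 39, 0.254), the unfolded protein response genes (0 of 18, 0.254) and the ATF4 genes (0 of 29, 0.657) were not past it either. Nor were the contractile genes (0 of 17, 0.657), the Hox and imprinted genes (0 of 28, 0.657) and the mitochondrially encoded genes (0 of 13, 0.667).

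None of the tested markers of other cell types was called. Macrophage and leukocyte markers, with 0 of 9 called (camera adjusted p = 0.855), lay 0.44 and 0.47 above the control mean in control replicate 3 and STING KO replicate 1. In the remaining libraries they lay between -0.45 and 0.01. Adipocyte, muscle and neural markers had 0 of 9 called, but their scores did not overlap between the groups: -0.04, 0.00 and 0.04 in control and 0.21, 0.25 and 0.19 in STING KO (camera adjusted p = 0.0558, just outside the threshold; fry adjusted p = 0.177). Of the epithelial and endothelial markers 4, and of the histone genes 3, were above the minimum, too few for a test, and 0 of either were called. The same 2 libraries also held transcripts typical of hepatocytes: Alb, serum albumin, was at 2780 and 2552 normalized counts there and at 101 to 268 in the other 4. Lcn2 within the NF-kB list was also at its highest of each group in these 2 libraries, as was C3 (585 and 427, against 95.4 to 143).

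**Figure D3:**
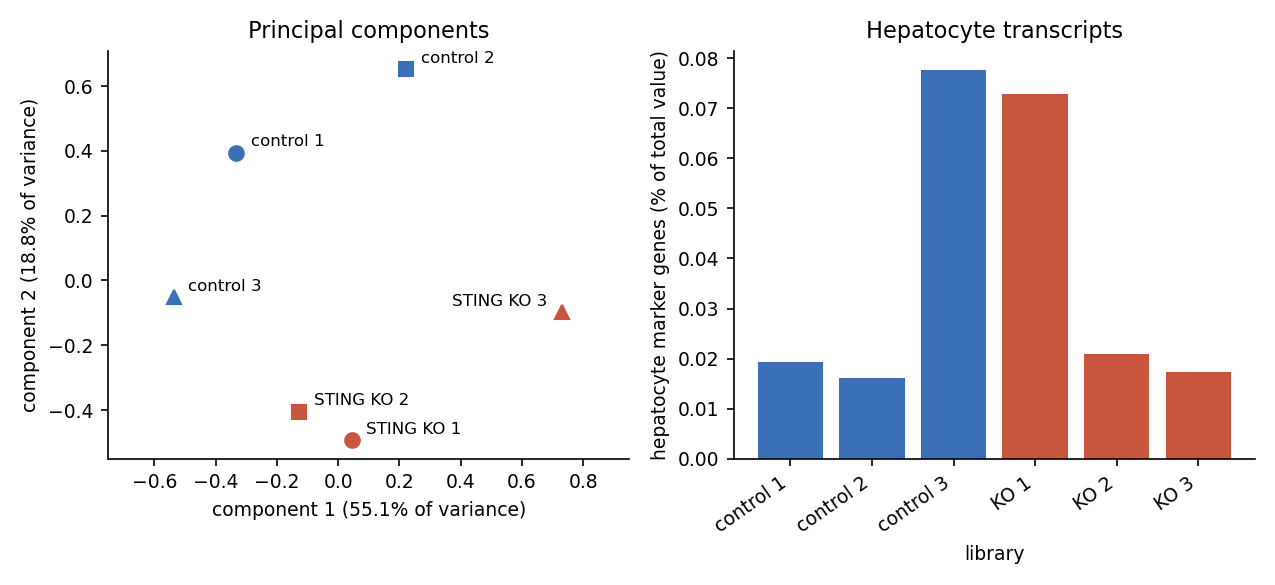
Left, the first 2 principal components of the log2 values of 9815 genes, with control in blue and STING KO in red. Right, the summed hepatocyte marker genes as a percent of the total of each library, at 0.0776% and 0.0728% in control replicate 3 and STING KO replicate 1 and at 0.0161% to 0.021% in the others. The sums include Fah, which was at 1389 to 1694 normalized counts in every library.

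With 3 samples against 3 the exact permutation test cannot give a p under 0.1, so for the classes that report on RNA composition it cannot decide. Mitochondrially encoded genes held 3.52 ± 0.0907% of the total in control and 3.43 ± 0.0701% in STING KO (SD, n = 3 each, exact p = 0.2). Ribosomal protein genes held 1.93 ± 0.137% and 2.10 ± 0.172% (exact p = 0.3). Histone genes held 0.00325 ± 0.000141% and 0.00382 ± 0.000235% (SD, n = 3 each), with no overlap between the groups (0.0031% to 0.00339% and 0.00362% to 0.00408%) and the smallest exact p possible, 0.1. The 10 genes with most counts held 5.34 ± 0.105% and 5.36 ± 0.122% (exact p = 1). Adjusted over these 4 classes, the exact p were 0.4, 0.4, 0.4 and 1.

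All 32 called genes had groups that do not overlap, which 12.1% of all tested genes had and chance gives for 10%. At an unadjusted p at or under 0.05, limma gave 397 genes higher and 394 lower. limma-voom called 0 higher and 30 lower, 29 of them shared with the 32. The authors' deposited table has 35 lower and 6 higher (Ndrg1, Car9, 2610528A11Rik, Txnip, Selenbp1 and Gsta4), and 30 of its 41 genes are shared. Without both libraries that hold hepatocyte transcripts 13 genes were called, 12 of them among the 32, and without control replicate 1 there were 21. The first principal component, with 55.1% of the variance, did not follow genotype: its ends were control replicate 3 (-0.537) and STING KO replicate 3 (0.731), while control replicate 2 lay at 0.222 and STING KO replicate 2 at -0.128. On the second component, with 18.8%, the control libraries (0.395, 0.652 and -0.0513) lay above the STING KO libraries (-0.493, -0.405 and -0.0971).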

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

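TMM and total scaling, limma-voom with default library sizes or a block, the GC and length correction, the added covariates and the fit without 2 libraries were chosen after seeing the data, and the rest before. For lists, only the estimated correlation, the count minimum, the replicate block and leaving out 1 library were fixed before. Sting1 and the other called genes kept a negative sign under every alternative run for them. Of 700 gene values under an alternative, 581 stayed on their side of the threshold, 119 were no longer past it and 0 turned sign. Of 504 list values, 473 stayed, 19 were no longer past it, 12 newly passed it and 0 called lists turned; 27 values of uncalled lists changed sign. The count of 32 lower genes was within 1.5 times under each alternative not named below.

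Replicate numbers, which set the block, do not pair the samples: deviations within a number correlated at -0.0261, -0.561 and -0.622. With the replicate block limma called 18 genes, all lower, and limma-voom with the block called 16.

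A fold threshold of 1.5 left 7 genes, and leaving out both libraries with hepatocyte transcripts left 13, with 2 samples per group. The GC and length correction called 4 genes higher (Txnip, Ankrd37, Pygl and Fcgrt) and kept 31 of the 32. A term for the split of the libraries described below called 2 higher (Txnip and Bnip3), and the authors' test 6. The first residual component as a covariate called 516 higher and 896 lower, 1412 in all. That covariate is estimated from the residuals it then removes, so its degrees of freedom are overstated and it was set aside; the split term shares this limit in part.

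Leaving out 1 library gave 21 to 35 genes in all, 21 to 35 lower and 0 to 2 higher. The 21 came without control replicate 1, and the 2 higher (Rpl13 and Ndufa4l2) without control replicate 2. Of the 32 genes, 20 were called whichever library was left out. The 12 others were Vmp1, Csf3, Cp, Nfkb2, Fgf7, Gypc, Irf1, Lif, Slpi, Col8a1, Pik3r5 and Tlr2.

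With an estimated correlation the adjusted p was 0.274 for glycolysis and hypoxia genes, 0.472 for ribosomal protein genes, 0.621 for NRF2 genes and 0.467 for p53 targets. The p53 targets were at 0.0644 with upper-quartile scaling, 0.0886 with the count minimum, 0.0594 with the replicate block, 0.05 (just above) with TMM, 0.0507 with the GC and length correction, 0.0506 with limma-voom and the block, 0.111 with the residual component and 0.206 without both libraries, and at 0.0369 to 0.208 leaving out 1. Leaving out control replicate 3 (0.164) or STING KO replicates 1 (0.0599) or 2 (0.208) ended the call. NRF2 genes were at 0.0507 with the correction and 0.0762 with the split term, and at 0.00296 to 0.336 leaving out 1, with the call lost without control replicate 1 (0.126) or STING KO replicate 3 (0.336). With an estimated correlation the extracellular matrix, cholesterol and adipocyte lists were each at 0.467, and extracellular matrix genes at 0.399 with the GC and length correction as well. With the preset one, extracellular matrix genes newly passed, as higher, at 0.0265 with the correction, 0.0275 with the split term and 0.0367 without both libraries, and ran from 0.0149 (without control replicate 3) to 0.392 leaving out 1 (0.0369 without STING KO replicate 3). Cholesterol genes newly passed, as lower, at 0.0253 with no filter and 0.0233 with a pseudocount of 1 and no filter, and ran from 0.0293 (without control replicate 3) to 0.21 leaving out 1 (0.0428 without STING KO replicate 3). Adipocyte, muscle and neural markers newly passed, as higher, at 0.0482 with the replicate block, 0.0433 with limma-voom and 0.045 with limma-voom and its default library sizes. The mitochondrial share difference went from -0.091 to 0.00451 percentage points without the 10 genes with most counts, 4 of which are mitochondrial. Except where stated, the cause was not tested.

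A count test and a rerun of the authors' test were planned and not run, since the values are normalized; median-of-ratios scaling is what the deposited values already carry.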

Other observations

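The tests of liver composition, of genotype for the hepatocyte transcripts and of unedited cells were chosen only after the results they measure were seen, as were the marker list and the GC and length correction themselves; the list tests had been looked at before these explanations were written down. Beyond the comparison above, Stat3, a transcription factor activated by interleukin-6 family cytokines, was just outside the threshold at 2486 ± 76.6 normalized counts in control and 1983 ± 92.8 in STING KO (SD, n = 3 each; limma adjusted p = 0.0554). In the authors' deposited table Stat3 is past it (adjusted p = 0.000705). Micall2, Susd6 and Itpripl2 are among the genes lower in that table and not called by limma. Slpi and Tlr2 are called by limma and not in that table.

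Transcripts typical of hepatocytes were high in control replicate 3 and STING KO replicate 1, where the 74 markers that reach 10 normalized counts in a library summed to 0.0776% and 0.0728% of the total. Fah, 1 of these markers, did not follow the pattern and was at 1389 to 1694 normalized counts in all 6 libraries. The marker sums of the other 4 libraries were 2333 to 3016, so the sums understate the contrast seen in most markers. Of the 50 of these 74 markers whose values had not been looked at, 43 (86%) had a mean in the 2 libraries of at least 3 times that of the other 4. RNA or reads from liver tissue may thus be the source. Among the markers looked at before, Alb (2780 and 2552), Trf, Ahsg and Apoa1 had the highest values in the 2 libraries. That 0% of the 50 markers not looked at before separate the genotypes follows from a pattern held by 1 library of each, so that test adds nothing. The summed shares themselves argue against STING genotype as the cause of this pattern. Control replicate 3 was at 0.0776% against 0.0194% and 0.0161% in the other control libraries. STING KO replicate 1 was at 0.0728% against 0.021% and 0.0174% in the other STING KO libraries. Whether the source had 1 composition in both libraries could not be decided. The ratio of the 2 libraries had a chi-square per degree of freedom of 3.82 over 66 of the markers. Of 1000 random sets of other genes matched on level, 19 reached it (median 1.58, central 95% from 1.05 to 3.21), a bound set after the value was seen. With each marker left out in turn it was at least 3.29 and above the bound of its own random sets. The ratio thus varied more over the markers than over most such sets. The sets were not matched on GC content or transcript length, which the first principal component follows (-0.537 and 0.0437 in these libraries). The spread therefore need not come from liver RNA of differing composition. Where such RNA entered stays open. Of the markers, 25 average 10 or more in the other 4 libraries and 0 are in the fixed lists. This does not show that the lists were untouched. The NF-kB list scored highest of each group in these 2 libraries, at 0.09 in control replicate 3 and -0.72 in STING KO replicate 1. With both left out, camera with the preset correlation still gave this list as lower (adjusted p = 1.4e-41). Alb was also close in control replicate 1 and STING KO replicate 2 (243 and 268 normalized counts). The same held for control replicate 2 and STING KO replicate 3 (101 and 113). Deviations of these pairs correlated at 0.385 and 0.748, and of control replicate 3 with STING KO replicate 1 at 0.441. The other pairs of unlike number ran from -0.379 to 0.364. No block on these pairs was run, so a pairing or batch under other numbers stays open.

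Among the list tests, the ribosomal list was higher in STING KO only by camera with the preset correlation. The glycolysis and hypoxia list was higher by that test and by fry. By camera with an estimated correlation the adjusted p were 0.472 and 0.274. The ribosomal scores of the groups overlapped, and those of the glycolysis and hypoxia list did not. Adjusted over the list alone, 0 of 49 ribosomal protein genes and 18 of 30 glycolysis and hypoxia genes were higher. A GC and length gradient runs through the libraries: across genes, which are not independent replicates, loadings of the first principal component had a Spearman rho of 0.455 with GC content and -0.37 with transcript length, and log2 fold changes had 0.241 and -0.222. After the correction the mean log2 fold change of ribosomal protein genes went from 0.125 to 0.089 (library SD 0.065 and 0.0649), 70.9% of its value (adjusted p = 4.59e-09; 0.467 with an estimated correlation), which lies between the bounds set for and against such a bias, so the bias and genotype cannot be told apart for this list. For glycolysis and hypoxia genes it went from 0.181 to 0.154 (library SD 0.0198 and 0.0557), 84.8% of its value, and camera with the preset correlation stayed past the threshold (adjusted p = 8.11e-15; 0.386 with an estimated correlation), which argues against the bias as the whole cause. An effect of genotype, or of culture conditions that differ between the groups, stays open and was not tested.

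For the genes called lower, changes of gene dosage were tested by chromosome and in windows of 1 Mb to either side. The labels do not say how the knockout was made. Any other difference between the control and STING KO cells, or between their cultures, goes with genotype in every library. For the called genes, such a difference and the loss of STING cannot be told apart. Over 20 chromosomes the median log2 fold change farthest from 0 was -0.032, which argues against chromosome copy number. The 27 other tested genes within 1 Mb of Sting1 had a median of -0.0271 with 0 called, from -0.684 (Reep2, adjusted p = 0.738) to 0.141 (Psd2). This argues against a local effect of the edit shared by most of these genes. It cannot exclude an effect on single neighbours. Of the 31 other called genes, 0 had neighbours within 1 Mb with a median of -0.3 or lower (medians from -0.0875 to 0.0464). This argues against focal changes that hold most of the neighbours within 1 Mb to either side. Smaller ones, such as one that holds only the adjacent Ccl2 and Ccl7, were not tested. The Sting1 RNA left is unlikely to come from unedited cells that express every gene at the control level, since 3 genes named by the rule (Cxcl1, Ccl2 and Ccl7) lie below it, with upper 95% limits of 6.43%, 12.9% and 19.1% of control against a lower limit of 23.2% for Sting1; transcripts of an edited allele were not tested. The 10 splits of the 6 samples are too few for a share under 0.05: 2 of them, the real one included, called as many genes as the real 32, and the highest other called 676. That split, control replicates 1 and 3 with STING KO replicate 2 against the rest, points to a structure of the samples other than genotype; after the GC and length correction it called 2 genes and the real split 45, and with the split as a term limma called 47, all 32 among them.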
